A study of Mus musculus with 18 samples.

How the data were processed

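Small RNA was sequenced from mouse adipose-derived stromal cells (ASC), a mesenchymal cell type grown from fat tissue, and from the extracellular vesicles (EVs) that these cells release. Per the labels' protocols, primed cells were exposed to interferon gamma for 24 h, and cells with or without this exposure were then kept in alpha MEM with 2% EV-depleted serum for 48 h. ASC RNA was isolated with TRIzol and RNeasy columns, EV RNA with a SeraMir column kit, and 5 microlitres of RNA went into each TruSeq Small RNA library. The 18 libraries form 4 groups: naive EV (n = 5), primed EV (n = 5), naive ASC (n = 4) and primed ASC (n = 4). Replicates carry the numbers of the source names. Nothing in the labels says that replicates came from separate animals, so p-values measure only the spread between these samples.

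The deposited values are raw counts per annotated miRNA hairpin locus, 1 file per library, with no normalization by the authors. Per the file headers, they were made with featureCounts 1.5.3 on the miRNA genes of Ensembl release 76, without regard to strand and without options for reads that map to several places or overlap several loci. The submitters' processing notes name bcl2fastq, STAR 2.0.4, Subread and featureCounts 1.45 on GRCm38, so header and notes give different featureCounts versions. Adapter trimming, length filters and alignment settings are not given in the sources used here. Counts are for hairpin loci, not mature arms, and RefSeq places more than 1 miRNA at the loci Mir126a, Mir142b, Mir451a, Mir24-2, Mir129-2 and Mir219a-1, which unstranded counting does not tell apart.

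The files list 2009 loci. Of these, 1899 matched GENCODE M21 by identifier, 1820 of them with identical coordinates. The other 110 held 5 of 17629699 counts in all. Names are GENCODE symbols, and 29 loci without a miRNA symbol took the RefSeq name at the same place. Mir146 is the symbol for miR-146a, Mir301 for miR-301a and Mir92-1 for miR-92a-1.

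Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Loci were kept by filterByExpr with the 4 groups, which left 245 loci holding 99.9573% of the counts. Libraries were scaled by TMM, and 1 model with a mean per group was fitted to all 18 libraries. Contrasts were tested with edgeR's quasi-likelihood test, and p-values were adjusted by Benjamini-Hochberg over the 245 loci with a threshold of 0.05. The contrasts were naive EV against naive ASC, primed EV against primed ASC, primed EV against naive EV, primed ASC against naive ASC, and the interaction, which is the priming effect in EVs minus that in ASC. Standard errors (SE) were derived from this fit as the absolute log2 fold change over the square root of the test's F value. They are approximate and can fail at low counts. Normalised values in CPM use the TMM-scaled library totals. Groups whose libraries do not overlap are called separated. Where a named locus had 1 to 3 counts over a group, and for Mir147 in ASC priming, the ratio of summed counts is given with its 95% interval, which covers counting error only. Other loci with few counts are given by their fitted log2 fold changes. Reads were counted without molecular identifiers.

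Gene lists, comparisons, tests and most alternatives were fixed before the data were examined. The 14 lists were let-7 family, inflammation and interferon responsive miRNAs, mesenchymal and fibroblast abundant miRNAs, haematopoietic and red cell miRNAs, endothelial miRNAs, liver miRNAs, striated muscle miRNAs, neural miRNAs, epithelial miRNAs, 17-92 clusters and paralogs, the Dlk1-Dio3 imprinted cluster, the Sfmbt2 repeat cluster, annotated loci with sequence like rRNA or other abundant RNA (rRNA-like loci), and AGO2 loaded Dicer-independent and mirtron loci. Lists were tested on weighted log2 CPM from limma's voom after TMM scaling, called voom values here. The tests were camera at a preset correlation of 0.01 between loci, adjusted over the lists of a comparison, camera with an estimated correlation, and fry. Medians and means of lists are of the edgeR log2 fold changes, so a camera direction can differ from them. Loci are named by a rule fixed in advance. For each comparison it takes the 10 largest increases and the 10 largest decreases among passing, separated loci with a mean of at least 10 CPM in the higher group. Where fewer than 5 loci pass, it takes all of these and the smallest p-values up to 10. It adds the 5 most abundant loci per group, up to 4 members per list, and Mir155, Mir146, Mir147, Mir21a, Mir221 and Mir222. Loci named on other grounds were chosen after their values were seen, and the text says so.

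Shares of counts were compared between groups with exact two-sided permutation tests in scipy 1.17.1. The family fixed in advance held 8 such tests. After the data were seen 12 more tests of this kind were added, on the haematopoietic share, slopes on hairpin GC content and library totals. All 20 were first adjusted together, and that value is given beside the value for the 8.

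Alternatives fixed in advance were relative log expression size factors, TMMwsp, library totals alone, DESeq2 1.42.0, limma-voom with sample quality weights, no low-count filter, a filter of CPM 10 in 4 libraries, only the groups compared, a replicate block by the number in the source name or by the leading number in the title, removal of the rRNA-like loci with the most abundant locus, and each of the 18 libraries left out in turn. Alternatives chosen after seeing the data were thinning every library to 180812 counts, leaving out primed ASC 3 and 4, removing the haematopoietic, endothelial and liver lists with Mir5108, Mir5112 and Mir5119, removing each library's trend with hairpin GC content, the title-number block with that GC correction, the title-number block for the lists, both blocks with an estimated correlation for the lists, and the haematopoietic share without each library. Before fits were compared, numbers were taken to pair libraries only where every same-number pair had a correlation over 0.1 after group means were removed. The title numbers met this in primed EV against naive EV alone, and the source-name numbers in none. The titles' numbers are not explained in the labels. Titles of naive EV 1 and naive ASC 1 carry a combined number, 1+2, and primed EV 1 and 5 share the number 5.

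The pipeline was tested on simulated data with the same groups and depths. With 40 changed loci, the shares of 4-fold changes called were 91.8% and 87.8% for naive and primed EV against ASC, 98.0% and 87.8% for priming in EVs and ASC, and 80.0% for the interaction. For 2-fold changes these shares were 44.0%, 46.0%, 56.0%, 31.3% and 28.6%. Naive and primed EV against ASC had over 160 calls and are closer to the simulation with 200 changed loci, where 95.9% and 93.5% of 4-fold and 66.1% and 60.3% of 2-fold changes were called, with calls at 1.83% and 4.59% of unchanged loci, against 0.500% and 0.402% with 40 changed. Replicate libraries were checked for duplicates, and none of 32 pairs within groups differed by as little as counting error gives (chi-square per degree of freedom from 19.7 to 488). Sequence reads, mature arms and other RNA classes were not analysed here.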

Results

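The data describe which miRNA hairpin loci were counted in EVs and in the ASC that released them, with and without interferon gamma priming. Total counts per library were 2245823, 778115, 1381872, 703422 and 613448 in naive EV 1 to 5, and 745228, 3052942, 1196469, 1363278 and 626951 in primed EV 1 to 5. They were 486237, 926183, 910964 and 520453 in naive ASC 1, 3, 4 and 5, and 895721, 303069, 180812 and 698712 in primed ASC 2 to 5. A library held counts at 303 to 423 loci. The first principal component, with 77.2% of the variance, parted EV from ASC libraries, and the second held 7.26%.

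A few loci made up most of the EV counts. Mir22, on chromosome 11 from 75463716 to 75463810 (GRCm38) in an exon of Mir22hg, took 27.3% ± 1.88 of counts (SD, n = 5) in naive EVs, 28.5% ± 1.22 (n = 5) in primed EVs, 15.6% ± 5.56 (n = 4) in naive ASC and 14.9% ± 1.5 (n = 4) in primed ASC. Mir143, a smooth muscle and fibroblast miRNA on chromosome 18 from 61649190 to 61649269 in intergenic sequence, took 22.6% ± 1.82, 22.5% ± 2.68, 13.9% ± 4.02 and 7.43% ± 0.654 in the same order. Mir21a, an abundant miRNA of growing and injured cells on chromosome 11 from 86584067 to 86584158 in the UTR of Vmp1, took 11% ± 0.823, 10.4% ± 0.694, 1.78% ± 0.439 and 1.44% ± 0.286. Mir191, Mir125b-1 and Mir125a were more prominent in cells, with means of 6.22%, 5.48% and 4.01% in naive ASC and of 1.52%, 0.826% and 0.603% in naive EVs. Mir10a and Mir10b, encoded within the Hox clusters, took 3.74% and 3.08% in naive EVs and 5.87% and 4.50% in naive ASC.

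The 5 most abundant loci of each library together held 67.7% ± 1.24 (SD, n = 5) of counts in naive EVs, 70.3% ± 0.938 (n = 5) in primed EVs, 48.4% ± 6.91 (n = 4) in naive ASC and 46.7% ± 0.306 (n = 4) in primed ASC. The naive EV share exceeded that of naive ASC by 19.3 points and the primed EV share that of primed ASC by 23.5 points, in both without overlap between libraries, and primed exceeded naive EVs by 2.53 points, with naive EV 1 (69.6%) above primed EV 1 (69.1%). Each had an exact permutation p of 0.0159. Over the 8 share tests fixed in advance the Benjamini-Hochberg adjusted p of these exact tests was 0.0423. Over all 20 exact tests computed, which include slopes on hairpin GC content and library totals, it was 0.0529, which misses the threshold. Primed and naive ASC differed by -1.65 points (exact permutation p = 0.743). The rRNA-like loci held 0.369%, 0.272%, 0.285% and 0.488% of counts in naive EVs, primed EVs, naive ASC and primed ASC, and none of the 4 differences passed (exact permutation p from 0.143 to 0.413).

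The first comparison asked how EVs from naive cells differ from the cells themselves. Mir21a was 8.38-fold higher in naive EVs (log2 fold change 3.07, SE 0.22, n = 5 and 4; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 5.55e-10), and Mir22 and Mir143 were 2.34-fold and 2.22-fold higher (SE 0.24 and 0.22 on the log2 scale). Mir451a, a red cell miRNA on chromosome 11 from 78073170 to 78073241, was 87.6-fold higher at 6.45 (SE 0.71; 5.75 without naive EV 4), and Mir126a, the endothelial miRNA within Egfl7 on chromosome 2 from 26591357 to 26591429, was 48.2-fold higher at 5.59 (SE 0.59). Mir145a, which neighbours Mir143 on chromosome 18 from 61647816 to 61647903, moved the other way and was lower at -2.79 (SE 0.23). Mir5099, a locus with sequence like abundant RNA on chromosome 12 from 36816205 to 36816278, was lower at -4.29 (SE 0.27). In all, 162 of 245 loci passed, 82 higher and 80 lower in EVs, and 132 differed at least 2-fold. Of all 245 loci 143 were separated, against 1.59% of loci by chance, and 137 of these passed.

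Other large increases in naive EVs were Mir5112, on the rRNA-like list, at 7.20 (SE 0.69), Mir142b at 6.4 (SE 0.60) and Mir223 at 6.29 (SE 0.72), the last 2 of blood cells. Mir5108 was at 5.70, Mir144 at 5.50, Mir301 at 5.32 and Mir19a at 4.86. Mir5119 had 1 count in all naive ASC libraries and 21 to 49 counts per EV library, a ratio of 131 (95% interval 23.2 to 5188). Other large decreases were Mir3072 at -4.01, Mir3102 and Mir193b at -3.22 each, Mir700 at -2.97, Mir184 at -2.87, Mir29b-1 at -2.70 and Mir667 at -2.50. Without 1 library Mir5108 moved to 6.47 (naive ASC 3), Mir3072 to -4.88 (naive EV 3) and Mir700 to -3.59 (naive EV 3), and all 3 kept their calls. Mir3095 had 2 counts in naive EVs and was 36.2 times higher in naive ASC by summed counts (95% interval 9.50 to 307). Among loci fixed for their link to inflammation, Mir147 was higher in naive EVs at 3.02 (SE 0.69; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.000768), a call lost after thinning to the shallowest library (adjusted p = 0.0577). Values without a call were -0.46 for Mir155, 0.82 for Mir146, 0.49 for Mir221 and -0.37 for Mir222.

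By list, 7 of the 9 haematopoietic and red cell miRNAs tested were higher in naive EVs, and 2 were lower, Mir15b at -2.05 and Mir342 at -1.01, which many cell types express. Adjusted over the list alone the counts were again 7 and 2. The share of counts on this list was 0.805% ± 0.476 (SD, n = 5) in naive EVs and 0.285% ± 0.0694 (n = 4) in naive ASC, a difference added to the tests after the data were seen (exact permutation p = 0.0159, and 0.0635 adjusted over the 12 tests so added). Naive EV 4 alone held 1.63%, and without it the naive EV mean was 0.598% and the difference 0.313 in place of 0.520 points. Counts of Mir451a were 894 to 4702 per EV library and 17 to 77 per ASC library, and those of Mir126a 2018 to 7491 and 42 to 163. Of 12 let-7 loci 6 were higher and 2 lower, and the same numbers held adjusted over the list alone, with Mir98 at 2.54, Mirlet7f-1 at 1.87 and Mirlet7b at -1.04. The median of the let-7 list was 0.41 and turned to -0.08 with library totals alone. Of 9 loci of the 17-92 clusters, which are linked to cell growth, 5 were higher and 0 lower, both over all loci and adjusted over the list alone, led by Mir19a at 4.86 and Mir20a at 3.82, and Mir17 was at 1.42. Of 35 loci in the Dlk1-Dio3 cluster, an imprinted region with many miRNAs, 8 were higher and 15 lower, as they were adjusted over the list alone, with Mir376a at 2.81, Mir667 at -2.50 and Mir485 at -1.67.

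Of 30 mesenchymal loci 10 were higher and 8 lower (10 and 7 adjusted over the list alone), including Mir214 at -2.17, Mir140 at -1.49 and Mir24-2 at 2.11. Of 20 inflammation loci 6 were higher and 5 lower, also adjusted over the list alone, including Mir125b-1 at -2.24 and Mir125a at -2.23. Of 10 epithelial loci 3 were higher and 1 lower (2 and 1 adjusted over the list alone), with Mir141 at 5.28 (SE 1.35) and Mir184 at -2.87, and limma-voom ended the call of Mir141 at 1.49, while without naive EV 4 it was at 4.09 and Mir200a, at 3.36 with all libraries, lost its call at 2.10. All 6 rRNA-like loci passed, 5 higher and 1 lower, also adjusted over the list alone. Of 3 neural loci 0 were higher and 2 lower, and of 5 AGO2 and mirtron loci 1 was higher and 3 lower, in both cases also adjusted over the list alone. Mir320 was at -0.84, while Mir702 at -1.60 and Mir877 at -1.01 lost their calls once the GC trend was removed (-1.06 and -0.65) or without naive ASC 5 (-1.20 and -0.67). Mir192 of the liver list was higher at 2.00, Mir467d of the Sfmbt2 cluster was lower at -1.33 (no call without naive ASC 3 at -1.14 or 5 at -1.09), and no striated muscle locus reached the filter. Against the other loci no list passed (camera on voom values, smallest adjusted p = 0.274). With library totals alone the median log2 fold change of all loci moved from -0.24 to -0.70, and 65 loci were higher and 116 lower, so directions are relative to the scaling. Medians of the inflammation list turned from 0.27 to -0.23 and of the epithelial list from 0.21 to -0.30 under that scaling. That of the mesenchymal list turned from -0.09 to 0.02 and 0.10 with relative log expression factors and TMMwsp.

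**Figure D1:**
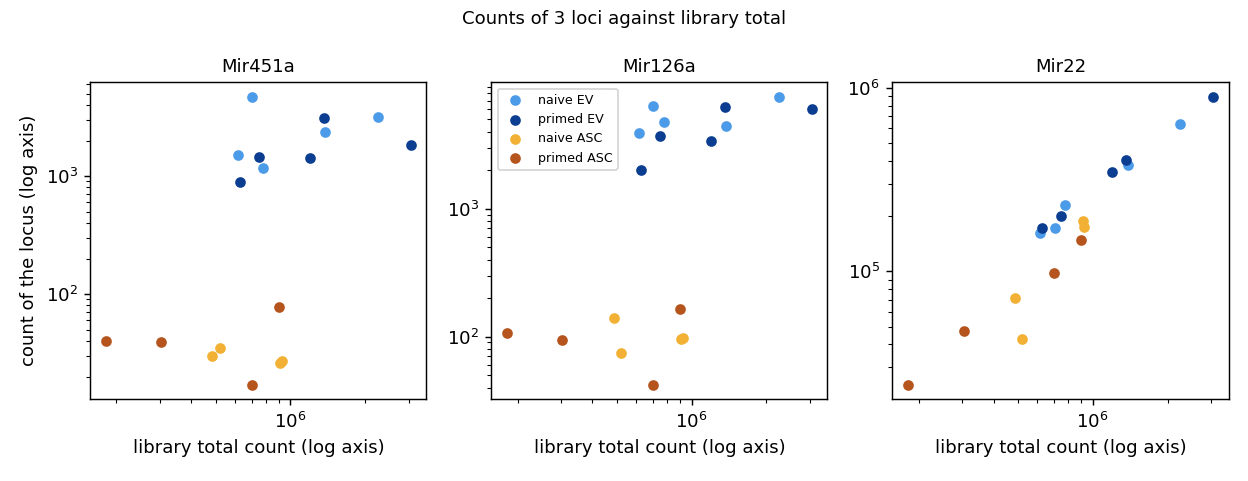
Raw counts of Mir451a, Mir126a and Mir22 in each of the 18 libraries on the vertical axis against the library's total count on the horizontal axis, both log scales. Mir451a lies between 894 and 4702 counts in EV libraries and between 17 and 77 in ASC libraries.

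**Figure D2:**
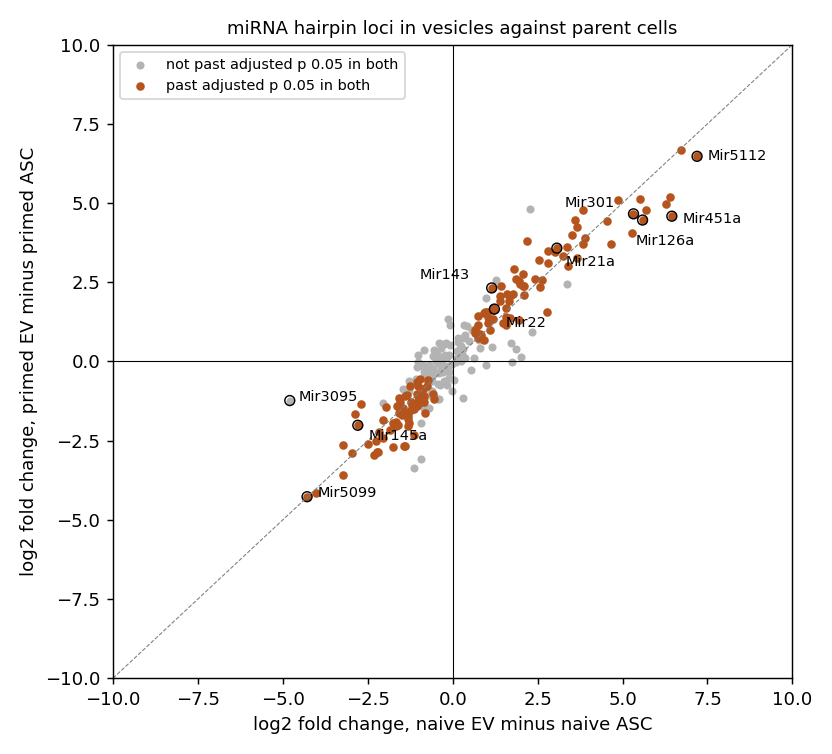
Each point is 1 of 245 miRNA hairpin loci, with the log2 fold change of naive EV over naive ASC on the horizontal axis and of primed EV over primed ASC on the vertical axis. Coloured points passed in both comparisons, the dashed line marks equal values, and Mir21a lies at 3.07 and 3.58.

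The next comparison put the same question to primed cells. Mir21a was 11.9-fold higher in primed EVs than in primed ASC (log2 fold change 3.58, SE 0.22, n = 5 and 4; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 7.47e-11), Mir143 was 4.99-fold higher at 2.32 (SE 0.23) and Mir22 was 3.14-fold higher at 1.65 (SE 0.24). Mir451a at 4.58 (SE 0.65), Mir126a at 4.46 (SE 0.56), Mir142b at 5.19 (SE 0.57), Mir144 at 5.14 (SE 0.62) and Mir223 at 4.97 (SE 0.69) were again higher, as were Mir5112 at 6.47 (SE 0.69), Mir19a at 5.11 and Mir301 at 4.66. Mir5099 at -4.27 (SE 0.28), Mir3072 at -4.15, Mir193b at -3.58, Mir7035 at -3.36, Mir1934 at -3.09, Mir129-2 at -2.95, Mir700 at -2.90, Mir125a at -2.86, Mir574 at -2.85 and Mir671 at -2.70 were lower. Without 1 library, with calls kept, Mir223 was at 5.59 (primed ASC 2) and 4.35 (primed ASC 5), Mir5112 at 7.37 and 5.87 (the same 2), Mir3072 at -5.49 and Mir7035 at -4.38 (primed EV 2), and Mir700 at -3.57 (primed EV 4). Here 167 of 245 loci passed, 88 higher and 79 lower, and 143 differed at least 2-fold. Of all 245 loci 131 were separated, against 1.59% of loci by chance, and 130 of these passed.

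Mir5119 had 1 count in primed ASC, a ratio of 95.6 (95% interval 17 to 3796), and Mir6538 also had 1 count there, a ratio of 51.7 (95% interval 9.10 to 2060), with 89 of its 113 EV counts in 1 library. Mir147 was higher in primed EVs at 3.45 (SE 0.58; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.84e-05) and Mir222 was lower at -0.74 (adjusted p = 0.00331). Mir221 was higher at 0.66 (adjusted p = 0.0164), a call lost in 5 of 15 alternatives and without naive ASC 1 or 3, primed ASC 2, 3 or 4 or primed EV 2 (adjusted p from 0.051 to 0.132), and its value was -0.01 with library totals alone. Mir155 at -0.05 and Mir146 at 0.42 did not pass. Of the loci higher in EVs, 74 were shared between the naive and primed comparisons, which use no library in common, where 29.5 would be shared if calls were independent. Of those lower, 64 were shared against 25.8, and 0 had opposite calls by edgeR's quasi-likelihood test. Both comparisons come from 1 fit and set the same RNA isolation methods against each other. An effect of the method would therefore be shared as well, and independence is not a neutral baseline. Across loci, which are not independent replicates, the log2 fold changes correlated with a Pearson r of 0.938 and a Spearman rho of 0.939.

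Of 9 haematopoietic loci 6 were higher and 2 lower in primed EVs, Mir15b at -1.84 and Mir342 at -1.08. The list held 0.514% ± 0.181 (SD, n = 5) of counts in primed EVs and 0.300% ± 0.0378 (n = 4) in primed ASC. The exact permutation p was 0.0635, and 0.152 adjusted over the 12 tests added after the data were seen. Without primed EV 2 the difference was 0.278 in place of 0.214 points (exact permutation p = 0.0286). Without any other library the unadjusted exact permutation p ran from 0.107 to 0.143. Of 12 let-7 loci 8 were higher and 1 lower, with Mir98 at 3.21, Mirlet7f-1 at 2.61 and Mirlet7b at -0.66, and with library totals alone 5 were higher and 4 lower. Of 9 loci of the 17-92 clusters 5 were higher and 2 lower, with Mir20a at 3.71, Mir17 at 2.40 and Mir106b at -0.74. Of 35 Dlk1-Dio3 loci 10 were higher and 8 lower, with Mir376a at 3.50, Mir485 at -2.04 and Mir667 at -2.60. Of 30 mesenchymal loci 12 were higher and 11 lower, and of 20 inflammation loci 8 were higher and 5 lower. Of 6 rRNA-like loci 2 were higher and 1 lower, of 3 neural loci 0 were higher and 1 lower, and of 5 AGO2 and mirtron loci 1 was higher and 3 lower. For each of these 9 lists the counts adjusted over the list alone were the same. Of 10 epithelial loci 3 were higher and 1 lower, but 0 and 0 adjusted over the list alone. Mir192 was at 2.46 and Mir467d at -1.62, both passing, and no striated muscle locus was tested. Against the other loci no list passed (camera on voom values, smallest adjusted p = 0.106, the let-7 family). With library totals alone the median of all loci moved from 0.02 to -0.69, with 58 loci higher and 118 lower, and the medians of the inflammation, mesenchymal, epithelial, rRNA-like and Dlk1-Dio3 lists turned negative, the last also with TMMwsp (-0.02).

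The third comparison asked what priming of the cells changed in their EVs. Mir147, an miRNA of the macrophage response to microbial signals on chromosome 2 from 122640803 to 122640881 in the UTR of AA467197, was 8.85-fold higher in primed EVs (log2 fold change 3.15, SE 0.49; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.000827). Its level was 129 ± 87.8 CPM (SD, n = 5) in primed and 14.7 ± 5.62 CPM (n = 5) in naive EVs, with all 5 primed libraries above all naive ones, and the call held in all 16 alternatives and all 18 fits without 1 library. Mir140, a cartilage miRNA within Wwp2 on chromosome 8 from 107551244 to 107551313, was 1.79-fold higher (0.84, SE 0.17; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.011), at 9030 ± 656 CPM (n = 5) against 5052 ± 949 CPM (n = 5), and again separated. These were the only 2 of 245 loci to pass, while 25 had an unadjusted p under 0.05. In all 6 loci were separated, against 0.794% of loci by chance.

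The call of Mir140 was lost in 6 of 16 alternatives and without naive ASC 1 or 3 or any 1 of primed ASC 2 to 5, with log2 fold changes from 0.53 to 0.97 and adjusted p up to 0.222. The count of 2 fell to 1 without each of those libraries, rose to 4 without naive EV 1 and to 8 without primed EV 2, and was 5 with DESeq2 and 11 with limma-voom. Loci with the next smallest p-values did not pass, among them Mir125b-2 at 0.59 (SE 0.16), Mir298 at -0.67 (SE 0.19), Mir31 at -0.98 (SE 0.29), Mir1934 at -2.21 (SE 0.64), Mir5114 at 1.37, Mirlet7c-2 at 0.56 and Mir125b-1 at 0.40. Mir3095 had 20 counts in primed and 2 in naive EVs, a ratio of 9.44 (95% interval 2.29 to 83.3), and did not pass either. Mir155, the miRNA of activated immune cells, was at 0.66 (SE 0.26; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.379), Mir146 at 0.14, Mir21a at 0.20, Mir221 at 0.22 and Mir222 at 0.17. With library totals alone Mir146, Mir21a, Mir221 and Mir222 took negative values, at -0.13, -0.09, -0.04 and -0.14.

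With the replicate block by title number 7 loci passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Naive EV 1, titled 1+2, shares its block only with naive ASC 1 and so adds little to this blocked contrast. Leaving out naive EV 1 without a block also raised the count above 2. The rise to 7 can therefore not be put down to pairing alone. Pairs of the same title number had correlations from 0.163 to 0.655 (5 pairs, 2 of which share naive EV 5), but only 2 of the 5 primed libraries correlated best with a naive library of their own number, and primed EV 2 correlated at 0.667 with naive EV 1 (titled 1+2) and at 0.584 with naive EV 2, so the support for this pairing is partial. Mir147 was at 2.84 (SE 0.47; adjusted p = 0.0021) and Mir140 at 0.90 (SE 0.17; adjusted p = 0.00317) with that block, as blocked values beside those above. The others were Mir31 at -0.92, Mir298 at -0.78, Mir125b-2 at 0.62, and Mir205 at -1.90 and Mir200b at -2.31, both epithelial miRNAs. Without the block Mir205 was at -1.68 and Mir200b at -1.97, far from passing (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.673 and 0.572). These 2 calls thus rest on the block. Together, the block and the GC correction gave 9 passing loci. With the block by source-name number 3 loci passed.

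By list, let-7 loci lay higher in primed EVs than other loci (camera on voom values, adjusted p = 0.00199, and adjusted p = 0.378 with an estimated correlation). However, 0 of 12 let-7 loci passed singly and 1 did adjusted over the list alone, Mirlet7c-2. Their median of 0.27 became -0.02 with library totals alone. The inflammation list lay higher too (camera adjusted p = 0.00921; adjusted p = 0.307 with an estimated correlation), with 1 of 20 higher and 0 lower, and 3 higher and 1 lower adjusted over the list alone, namely Mir147, Mir125b-2, Mir125b-1 and Mir31. The mesenchymal list (camera adjusted p = 0.0337; adjusted p = 0.378 with an estimated correlation) had 1 of 30 higher and 0 lower, Mir140, also adjusted over the list alone. Medians of both these lists turned with library totals alone, from 0.21 to -0.06 and from 0.26 to -0.03. The 17-92 list lay lower (camera adjusted p = 0.00921; adjusted p = 0.378 with an estimated correlation) with 0 of 9 passing, and 0 adjusted over the list alone, with Mir92-1 at -0.47 and Mir20a at -0.60. In the other lists 0 loci passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment and 0 did adjusted over the list alone, among them 9 haematopoietic, 10 epithelial, 35 Dlk1-Dio3, 6 rRNA-like, 3 neural and 5 AGO2 and mirtron loci, with Mir126a at -0.34, Mir192 at 0.05 and Mir467d at 0.63. With the title-number block camera called the epithelial list lower (adjusted p = 0.00234, against 0.434 unblocked) and the haematopoietic list lower (adjusted p = 0.0331, against 0.201 unblocked). Both calls were lost with an estimated correlation under that block (adjusted p = 0.261 for the epithelial and adjusted p = 0.424 for the haematopoietic list).

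**Figure D3:**
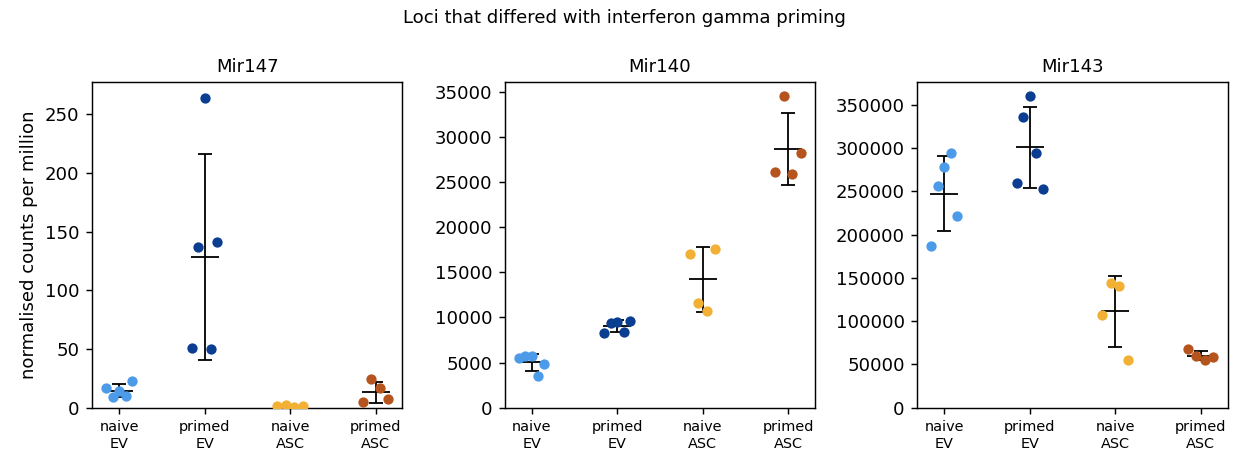
Normalised CPM of Mir147, Mir140 and Mir143 in each library of the 4 groups, with the mean and SD of each group. All 5 primed EV libraries lie above all 5 naive EV libraries for Mir147 and Mir140, and Mir143 averages 111569 CPM in naive and 60232 CPM in primed ASC.

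The fourth comparison asked what priming changed in the cells. Mir140 was 2.02-fold higher in primed ASC (log2 fold change 1.01, SE 0.19; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00469), at 28674 ± 4020 CPM (SD, n = 4) against 14230 ± 3576 CPM (n = 4). Mir125b-2, Mir125a and Mir125b-1, mouse relatives of worm lin-4, rose by 0.98 (SE 0.18), 0.82 (SE 0.18) and 0.68 (SE 0.16) on the log2 scale. Mir218-1, an miRNA in an intron of Slit2, was 3.68-fold higher at 1.88 (SE 0.39). Mir143 was lower at -0.89 (SE 0.23) and Mir351, an X-linked miRNA, at -1.07 (SE 0.23). Mir147 was 6.54-fold higher at 2.71 (SE 0.76; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0297), from 24 counts against 6, a ratio of 5.71 (95% interval 2.27 to 17.1).

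In all 25 of 245 loci passed, 13 higher and 12 lower, and 57 had an unadjusted p under 0.05. Of all 245 loci 28 were separated, against 2.86% of loci by chance, and 17 of these passed. Further increases were Mir7224 at 2.04, Mir1247 at 1.75, Mir6236 at 1.54, Mir671 at 1.07, Mir378a at 1.05, Mir423 at 1.04 and Mir34b at 0.86. Further decreases were Mir758 at -1.51 (-2.13 without primed ASC 2), Mir1983 at -1.47, Mir495 at -1.26, Mir487b at -0.95, Mir582 at -0.89, Mir98 at -0.83, Mir382 at -0.82, Mir541 at -0.80, Mir298 at -0.74 and Mir28a at -0.65. Of these, Mir671, Mir423, Mir298, Mir495 and Mir582 were outside the naming rule and were chosen after their values were seen. The calls of Mir125b-2 and Mir351 held in all 15 alternatives and all 18 fits without 1 library, while Mir541, Mir382 and Mir98 lost theirs in 9, 9 and 11 of 15 alternatives, with adjusted p up to 0.467, 0.331 and 0.295. The call of Mir147, primed ASC vs naive ASC, was lost with limma-voom and without naive ASC 3, 4 or 5 or primed ASC 3 or 4 (adjusted p from 0.0506 to 0.101 without 1 library, and 0.295 without both primed ASC 3 and 4). Values without a call were 0.25 for Mir155, 0.53 for Mir146, -0.30 for Mir21a, 0.05 for Mir221 and 0.54 for Mir222, and Mir221 was at -0.03 with library totals alone. The count of 25 fell to 6 without naive ASC 3 or 4, to 11 without primed ASC 3, to 12 without primed ASC 4, to 3 without both of these, and to 15 with only the groups compared, and was 53 with limma-voom.

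Of 20 inflammation loci 4 were higher and 0 lower, also adjusted over the list alone, namely the 3 Mir125 loci and Mir147. The list as a whole did not pass (camera on voom values, adjusted p = 0.409). Of 35 Dlk1-Dio3 loci 1 was higher, Mir1247, and 5 were lower, among them Mir758 and Mir487b (1 and 7 adjusted over the list alone). That list lay lower than other loci (camera adjusted p = 0.00206; adjusted p = 0.721 with an estimated correlation), and its 5 lower calls became 2 with relative log expression factors and 0 with TMMwsp. Of 30 mesenchymal loci 3 were higher, Mir140, Mir218-1 and Mir34b, and 1 was lower, Mir143 (3 and 2 adjusted over the list alone). Of 12 let-7 loci 0 were higher and 1 lower, Mir98 (0 and 0 adjusted over the list alone), and of 6 rRNA-like loci 1 was higher, Mir6236 (3 higher and 1 lower adjusted over the list alone). The rRNA-like loci held 0.701% of counts in primed ASC 3 and 0.665% in primed ASC 4, against 0.204% to 0.349% in the other 6 ASC libraries, and without these 2 libraries Mir6236, primed ASC vs naive ASC, was at 0.65 and lost its call (adjusted p = 0.503). In the haematopoietic, epithelial, 17-92, neural, and AGO2 and mirtron lists 0 loci passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 0 did adjusted over the list alone, with Mir451a at 1.28 (SE 0.63) and Mir17 at -1.07 (SE 0.35). Mir126a was at 0.79, Mir192 at -0.41 and Mir467d at 0.92. The 2 shallowest libraries of the study, primed ASC 3 and 4, were in this comparison. Both loci called for priming in EVs, Mir147 and Mir140, were also called in ASC, where 0.106 would be shared if calls were independent, and 19 of the 25 ASC calls had the same sign in EVs. Across loci, which are not independent replicates, the 2 priming effects had a Pearson r of 0.453 and a Spearman rho of 0.345.

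The last comparison tested whether priming acted differently on EVs and on cells. The smallest p-value was that of Mir143, whose priming effect was higher in EVs than in ASC by 1.17 on the log2 scale (SE 0.31; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.232), which did not pass. For Mir147, a locus with few counts in ASC, the difference was 0.44 (approximate SE 1.18), which does not show that the effects are alike. It took values from -0.38 to 1.30 over the alternatives. The difference for Mir125a, a locus that rose in ASC, was -0.63 (SE 0.24) and did not pass. With edgeR 0 of 245 loci passed, while 26 had an unadjusted p under 0.05, and DESeq2 called 3 and limma-voom 5. Other values without a call were 3.56 for Mir3095, 0.74 for Mir28a, 1.00 for Mir382, -1.79 for Mir6236, 1.49 for Mir1983, -1.46 for Mir218-1, 1.21 for Mir199a-2, 1.00 for Mir582 and 0.74 for Mirlet7f-1. Mir155 was at 0.41, Mir146 at -0.39, Mir21a at 0.51, Mir221 at 0.17 and Mir222 at -0.37, and Mir221 was at -0.02 with relative log expression factors. Without naive ASC 5 the count was 1.

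The let-7 list had a higher priming effect in EVs than in ASC relative to other loci (camera on voom values, adjusted p = 0.00162, and adjusted p = 0.539 with an estimated correlation). So did the Dlk1-Dio3 list (camera adjusted p = 0.0112, and adjusted p = 0.622 with an estimated correlation). No member passed singly, and 0 did adjusted over the list alone in either. Adjusted over the list alone, Mir143 passed in the mesenchymal list (1 higher, 0 lower) and Mir6236 in the rRNA-like list (0 higher, 1 lower), and 0 loci passed in the inflammation, haematopoietic, epithelial, 17-92, neural, and AGO2 and mirtron lists. Mir126a was at -1.13, Mir192 at 0.46 and Mir467d at -0.28. In the naive comparison of EVs with ASC, the mesenchymal list had a median of -0.09 and a mean of 0.08, the AGO2 and mirtron list -0.84 and 0.58, and the epithelial list a median of 0.21 with a camera direction of lower. In the interaction, the inflammation list had a median of 0.18 with a camera direction of lower, and the 17-92 list a median of 0.08 and a mean of -0.03. In ASC priming the mesenchymal list had a median of -0.02 and a mean of 0.07, and in EV priming the neural list -0.19 and 0.05.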

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

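In this part the test of a fixed amount per library was chosen after its result was seen, and the GC correction was added after the data were seen. A library stood apart where its gap to the nearest of its group was too large a part of the group's range for Dixon's test. This happened in 18 of 248 groups tested, where chance, which gives about 1 in 20 groups, gives about 12.4.

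Naive EV 4 held 1.63% of its counts on the haematopoietic and red cell list, against 0.464% to 0.771% in the other naive EVs. Its levels of Mir451a (7810 CPM against 1389 to 2508), Mir142b (6677 CPM against 1630 to 3038), Mir144 (904 CPM against 216 to 326) and Mir223 (355 CPM against 75.0 to 155) were above all others of its group. These results belong to 1 set of loci and are not independent of each other. Naive EV 5 had fewer counts in all (613448 against 703422) but a share of 0.771%. Naive EV 4 also had the lowest Mir218-1 of its group (4.98 CPM against 21.7 to 28.4).

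The 7 haematopoietic and endothelial loci higher in EVs than in ASC in both comparisons (Mir451a, Mir126a, Mir142b, Mir144, Mir150, Mir223 and Mir486) were weighed as the first pattern. Over all 10 tested members of the 2 lists, with Mir15b and Mir342 lower in EVs, the lower of the median log2 fold changes was 4.09 (median SE 0.57), and after removal of each library's GC trend 4.16 (median SE 0.57), which argues against that trend as the whole cause. Counts of these 7 loci followed the counts of all other loci across the 10 EV libraries with a median slope of only 0.263 (95% bootstrap interval -0.200 to 0.841). This was against 1.00 for other loci of like abundance and below all of 10000 random lists of such loci. Those lists drew loci singly, while haematopoietic loci vary together between libraries (estimated correlation 0.573). The rank therefore overstates the evidence, and the interval over libraries is the better guide. The median slope was 0.295 within naive EVs and 0.347 within primed EVs. Naive EV 1 and primed EV 2, the deepest libraries of these groups, have titles that begin with 1+2 and 2. No slope was fitted without them, so a structure that follows the title numbers may bear on it. A low slope was not particular to the 7 loci. Mir5108, Mir5112 (on the rRNA-like list) and Mir5119, also higher in EVs and on neither of the 2 lists weighed here, had a median of -0.141. A candidate explanation is a roughly fixed amount of the 7 miRNAs per EV library from outside the ASC, such as serum, other cells or reagents. It takes library totals to follow the amount of RNA in the library, which was not tested. Counts of Mir451a, though, ranged as widely as the 5.03-fold range of depth. Counts per EV and ASC library were 2018 to 7491 and 42 to 163 for Mir126a, 894 to 4702 and 17 to 77 for Mir451a, and 1211 to 4020 and 26 to 62 for Mir142b. All 7 also had counts in ASC, Mir223 and Mir451a stand on another list too, the labels read here name no sort, and selective release of these miRNAs by the cells stays open as untested.

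Other libraries that stood apart are given as values. Primed EV 1 had 289 CPM of Mir1247 against 97.3 to 146 in its group. Naive ASC 1 had 240 CPM of Mir126a against 86.7 to 91.4, and 51.5 CPM of Mir142b against 31.1 to 34.6. Naive EV 3 had 155 CPM of Mir146 against 39.7 to 64.8. Primed ASC 2 had 35.4 CPM of Mir146 against 66.4 to 72.6, 719 CPM of Mir193b against 1067 to 1129, and 606 CPM of Mir3102 against 457 to 481. Primed EV 4 had 2778 CPM of Mir222 against 2291 to 2376. Naive EV 1 had 28.0 CPM of Mir7224 against 6.64 to 11.6. Naive ASC 4 had 0.90 CPM and primed ASC 4 had 4.15 CPM of Mir5119, and primed ASC 2 had 0.91 CPM of Mir6538, each from 1 count where the other libraries of the group had 0.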

How the results depend on the processing

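Alternatives chosen after seeing the data were thinning, leaving out primed ASC 3 and 4, removal of the blood, endothelial and liver lists, the GC correction, the title-number block for the lists or with that correction, and both blocks with an estimated correlation for the lists. The numbers of loci called for naive EV vs naive ASC and primed EV vs primed ASC ran from 125 to 181 and from 133 to 176 over the alternatives, with at least 124 and 131 of the same loci, and from 147 to 164 and 154 to 168 without 1 library, but their split by direction moved with library totals alone, to 58 higher in primed EV vs primed ASC. Unadjusted exact p-values of the share tests (5 most abundant and rRNA-like loci) kept their side of the threshold without any 1 library, but the adjusted p for the 5 most abundant loci in 3 comparisons was 0.0423 over 8 tests and 0.0529 over all 20, which misses it. Over the values of named loci, 5147 kept direction and call, 235 lost a call, 59 gained one and 36 turned. Where no cause is given below, the cause was not tested.

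For primed EV vs naive EV, 1 locus passed with TMMwsp, with library totals alone, with CPM of 10 in 4 libraries, with the rRNA-like and most abundant loci removed, after thinning and without primed ASC 3 and 4, while 5 passed with DESeq2, 11 with limma-voom, 8 without the low-count filter, 7 with the title-number block and 9 with that block and the GC correction. Without 1 library it was 1 to 8. For primed ASC vs naive ASC, 53 passed with limma-voom, 15 with only the groups compared, which leaves fewer libraries for the spread, 3 without primed ASC 3 and 4, which leaves 2 primed libraries, and 6 to 33 without 1 library. For the interaction, 3 passed with DESeq2, 5 with limma-voom, 3 without the filter and 0 to 1 without 1 library.

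With fry, which tests a list's own direction and not against other loci, lists without a camera call had adjusted p-values in naive EV vs naive ASC of 0.00514 (neural and let-7), 0.00727 (17-92) and 0.00959 (haematopoietic), and in primed EV vs primed ASC of 0.000719 (neural), 0.0215 (17-92), 0.0485 (haematopoietic), 3.51e-05 (let-7) and 0.0235 (AGO2 and mirtron). In primed EV vs naive EV the calls were lost with an estimated correlation (adjusted p = 0.378 for mesenchymal, 17-92 and let-7, and 0.307 for inflammation), with fry (0.196 mesenchymal, 0.296 17-92, 0.163 let-7, while the inflammation list kept its call at 0.0315) and with relative log expression factors (0.0534 for the list mesenchymal and fibroblast abundant miRNAs, primed EV vs naive EV). The epithelial list gained a call with the source-name block (0.0166) and the title-number block (0.00234), and the haematopoietic list with the latter (0.0331), but neither had one under a block with an estimated correlation (adjusted p = 0.299 and 0.261 for the epithelial and 0.616 and 0.424 for the haematopoietic list with the source-name and title-number block). Under those 2 settings the mesenchymal, 17-92 and let-7 lists were at 0.299 and 0.324 and the inflammation list at 0.299 and 0.261. The Dlk1-Dio3 call in primed ASC vs naive ASC was lost with an estimated correlation (0.721, and 0.52 and 0.29 with the source-name and title-number block) and fry (0.316). In the interaction the haematopoietic list gained a call with the source-name (0.0193) and title-number block (0.0104), and lost both with an estimated correlation (adjusted p = 0.418 and 0.385). The let-7 list (0.539 estimated, 0.418 and 0.385 with the 2 blocks, 0.262 fry) and Dlk1-Dio3 list (0.622 estimated, 0.418 and 0.195 with the 2 blocks, 0.39 fry) lost theirs.

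Values that turned in sign were small, and 1 of them, Mir221 in primed EV vs primed ASC, had a call. With library totals alone Mir221 was at -0.00328 in naive EV vs naive ASC, -0.015 in primed EV vs primed ASC, -0.042 in primed EV vs naive EV, -0.030 in primed ASC vs naive ASC and -0.011 in the interaction. Under the same scaling Mir146 was at -0.31 in primed EV vs primed ASC and -0.13 in primed EV vs naive EV, where Mir21a was at -0.087 and Mir222 at -0.14. Mir155 in primed EV vs primed ASC was at 0.070 with limma-voom, 0.040 without the filter and from -0.29 to 0.14 without 1 library, and Mir146 there at -0.30 with the GC correction. Mir146 in primed EV vs naive EV was at -0.16 after thinning. Mir221 in primed ASC vs naive ASC was at -0.025 with limma-voom. In the interaction Mir146 was at 0.24 with limma-voom, Mir147 at -0.38 after thinning, and Mir221 at -0.021 with relative log expression factors, -0.022 with DESeq2 and with the rRNA-like and most abundant loci removed, -0.097 with TMMwsp, -0.060 after thinning and -0.094 without primed ASC 3 and 4. Without 1 library, Mir146 ran from -0.15 to 0.66 in primed EV vs naive EV and from -0.78 to 0.034 in the interaction, Mir221 from -0.15 to 0.27 in primed ASC vs naive ASC and from -0.13 to 0.30 in the interaction, and Mir147 from -0.16 to 0.77 in the interaction.

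Depth limits loci with few counts: after thinning to 180812 counts 190 loci were tested in place of 245.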

Other observations

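In this part the neighbouring loci, Mir30e and Mir30d were chosen after their values were seen. The slopes on GC content, the GC correction, thinning and the fit without primed ASC 3 and 4 were added after the data were seen. The splits restricted by title-number pairs were not among the tests fixed in advance.

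Some miRNAs that lie side by side in the genome differed in opposite directions between EVs and cells. With 82 of 245 loci higher and 80 lower in naive EVs, some such pairs can arise by chance. No count of all neighbouring pairs is given here. Mir143 was higher in naive EVs at 1.15 (SE 0.22) and in primed EVs at 2.32 (SE 0.23), while its neighbour Mir145a was lower at -2.79 (SE 0.23) and -2.02 (SE 0.23). In the Mir23a cluster, Mir27a at 1.18 and Mir24-2 at 2.11 were higher in naive EVs and Mir23a was lower at -0.95, and the primed values were 1.63, 2.09 and -0.55. All of these values passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (n = 5 and 4 in each comparison). Differences between neighbours do not depend on how libraries are scaled, but the values themselves do. With library totals alone the primed values were 1.60 for Mir143, -2.73 for Mir145a, 0.91 for Mir27a, 1.36 for Mir24-2 and -1.28 for Mir23a. Mir24-2 in primed EVs was at 2.72 with the GC trend removed. The directions of these neighbours held in all 33 fits under other settings or without 1 library. So did the calls, except that of Mir23a in primed EVs. It was lost without the low-count filter, without primed ASC 3 and 4 and after GC correction (adjusted p up to 0.251). The loci were counted without options for reads that map to several places. Mature sequence shared with other loci may therefore bear on these values, and its part was not tested. Mir144 and Mir451a, also neighbours, were both higher in naive EVs, at 5.50 and 6.45 (Mir451a 5.75 without naive EV 4), and in primed EVs, at 5.14 and 4.58. Without primed ASC 3 and 4 the primed values were 5.96 and 5.50 and with library totals alone 4.39 and 3.79, that of Mir144 was 4.32 with the GC trend removed, and all kept their calls.

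Mir30e, outside every list fixed here, was 9.45-fold higher in naive EVs (log2 fold change 3.24, SE 0.23, n = 5 and 4) and 10.1-fold higher in primed EVs (3.34, SE 0.23). Mir30d of the same family was lower at -0.85 and -1.09. With library totals alone the primed values were 2.60 for Mir30e and -1.80 for Mir30d, with both calls kept. The slope of log2 CPM on hairpin GC content was -0.0195 per percent GC in naive EVs and 0.0169 in naive ASC, and -0.0238 in primed EVs and 0.0371 in primed ASC (exact permutation p = 0.0159 for each pair, and 0.0635 adjusted over the 12 tests added after the data were seen).

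EV and ASC libraries differed in most loci tested, which was weighed as the second pattern. Of the calls at least 85.6% remained in both comparisons once each library's GC trend was removed, at least 91.4% once the rRNA-like loci and the most abundant locus were removed, and at least 76.5% after thinning to the shallowest library. None of these 3 therefore accounts for the whole difference. The RNA isolation method cannot be told apart from the compartment, since EVs and cells each had their own kit and 0 groups hold libraries of both compartments. Differences between EVs and cells could come from either or both.

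Primed and naive ASC differed in 25 loci, the third pattern weighed, and rRNA-like loci held 0.701% and 0.665% of counts in primed ASC 3 and 4 against 0.204% to 0.349% in the other 6 ASC libraries. Of these calls 68.0% remained after thinning, which argues against the low depth of primed ASC 3 and 4 as the whole cause, and 76% after removal of the GC trend. Without primed ASC 3 and 4 only 3 of the 25 calls remained. All 25 kept their sign, and their median absolute log2 fold change went from 1.01 (median SE 0.26) to 0.86 (median SE 0.30), 85.1% of the value with them. The 25 loci were selected with all libraries and the refit reuses the others. Kept signs and sizes were thus partly fixed in advance and are not separate support. Smaller fold changes and larger errors with 2 primed libraries both lower the test, and their parts in ending the calls were not separated. An effect of interferon gamma may underlie these differences, as a hypothesis found and tested on the same samples, and other differences between these cultures stay open.

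Other splits of the same libraries into groups of the same sizes were fitted for each comparison. For naive EV against naive ASC, 1 of 100 splits, the real one with 162 loci, gave as many, and the highest other gave 126, with naive EV 1 on the side of the 4 ASC libraries. For primed EV against primed ASC, 1 of 100 splits gave as many as the real 167, and the highest other gave 118, again with 1 EV library beside the 4 ASC libraries. For primed against naive ASC, 1 of 35 splits gave as many as the real 25, and the highest other gave 11. For these 3 counts the share of splits with as many loci was under 5%, unadjusted over the comparisons. The test takes libraries as exchangeable, which the labels do not settle. For primed against naive ASC, 1 of 35 is the lowest share this test can give, and the count fell to 6 without naive ASC 3. Chance is thus not called excluded there. For the interaction the real count was 0 and the highest other 4, so all 100 splits had to give at least as many and this test says nothing about chance (with edgeR 26 loci had an unadjusted p under 0.05, and DESeq2 called 3 and limma-voom 5).

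For primed EV against naive EV, 4 of the 100 splits fitted, of 126 possible, gave at least the real 2 loci. This share is under 5%, but a count of 2 does not set the real split apart, so chance is not called excluded. The highest other gave 9, several times the real count, and the next gave 7 and 5. All 3 put naive EV 1, naive EV 2 and primed EV 2 on the same side, the EV libraries whose titles begin with 1+2 or 2, which leaves open a structure of the samples that follows the title numbers, though only 2 of the 5 primed EV libraries correlated best with a naive EV library of their own number. With the replicate block by title number, in which naive EV 1 shares its number with no primed EV library, 7 loci passed. The real split parts 5 of the 6 pairs of EV libraries with the same title number, 3 of which lie among the 3 libraries of number 5. Among the 24 splits that part as many pairs, the real one gave 7 loci with the block and the highest other 2, and without the block 2 and 1. This restricted set was not fixed in advance, and the wider set did not set the real split apart. It is therefore not separate support for an effect of priming.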
